A study of Rattus norvegicus with 40 samples.

How the data were processed

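RNA from circulating and kidney T cells of SS rats was sequenced by the submitters in 40 libraries, 4 for each of 10 groups, each library from a pool of 3 rats per the labels. Per the submitters' processing notes, reads were trimmed with cutadapt and Trim Galore 0.2.5, aligned to build rn5 with TopHat and TopHat2 2.1.1, assembled with Cufflinks 2.2.1 and compared with Cuffdiff. The deposited files are 15 Cuffdiff tables of 31677 gene models each, of which 14949 carry a symbol. Per the file headers, expression in these tables is FPKM, 1 value per group, and the authors computed it with Cuffdiff. The deposited test statistic is the Cuffdiff score of each comparison, with its p-value and q-value per the file headers. The smallest deposited p was 5e-05. Values per library are not used here, so no standard deviation, leave-one-out run, other split of the libraries or check for outlying libraries was possible, and the depth of the libraries and the precision it gives are unknown.

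Of the tables, 5 compared groups within circulating cells, 5 compared the same groups within kidney cells, and 5 compared kidney with circulating cells of the same group of rats. Pool numbers are shared between the tissues, but whether the pools held the same rats is not known. Each was oriented as HS over LS, SS/CRL over SS/MCW, 10 over 7 weeks or kidney over circulating, which reversed 1 table. The deposited fold change column was not used, because a spreadsheet had altered part of it, and log2 fold changes were computed from the deposited FPKM. A symbol had become a date in 25 gene models, 355 gene models carried more than 1 symbol, and 68 symbols stood on more than 1 gene model. A gene model was called where the authors' q was under 0.05 and the status was OK. No fold is given where a group was listed at 0.

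Lists of genes, 45 in all with 746 members, were fixed before the data were examined, as were the comparisons, the tests, most of the alternatives and the rule for naming genes. Of the members 700 were matched to a gene model, 26 of them by a synonym or another case. For each list the calls were counted over all genes and with Benjamini-Hochberg adjustment over the list alone. The calls were compared with those of other genes by Fisher's exact test adjusted over the lists. The median log2 fold change of members with at least 1 FPKM in the higher group was ranked among 10000 random lists matched on mean expression in 10 bins. Genes of a list can move together and are not replicates. The Fisher p-values and the ranks thus describe the lists and do not measure variation among rats. A list is described in the text where its members were called or where it bears on the cells studied. Genes named were the 5 largest rises and 5 largest falls among called genes with a symbol, at least 5 FPKM in the higher group and a value above 0 in both, and up to 4 called members of each list. Also named were Cd3e, Cd4, Cd8a and Ptprc always, up to 3 of the most expressed members of lists described without a call and, for differences, the 5 largest in each direction. Umod, Fos and Lyz2 in the comparison of kidney with circulating cells, and a few list members beyond this rule, were chosen after their values were seen. Some genes that meet the rule are not reported here.

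A difference between 2 effects was tested with a z formed from the difference of the log2 fold changes and standard errors equal to the log2 fold change divided by the deposited test statistic, with a normal p and Benjamini-Hochberg adjustment. On simulated data with the same standard errors this test recovered 0%, 0.5% and 9.5% of differences of 1, 2 and 3 log2 units for kidney salt effects and 0.5%, 34.5% and 68% for circulating ones. The list test placed 5 of 100 unchanged simulated lists and 100 of 100 lists shifted by 1 outside percentiles 2.5 to 97.5. Overlaps of comparisons that share a group had their correlation and covariance set against 100 simulated draws in which no group differed.

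The alternatives were a q under 0.01, a minimum of 1 FPKM with the deposited p adjusted again, a normal p of the test statistic with and without recentring on the median of genes with at least 5 FPKM in both groups, and a pseudocount of 1 on FPKM. Further alternatives were lists without the filter, with the mean or with unmatched random lists, a minimum of 5 FPKM for differences and correlations, and each kidney and circulating comparison left out in turn. Gene models called higher in kidney, or higher in circulating cells, in all 5 comparisons between the tissues are named kidney-high and circulating-high. Chosen after the data were seen were the calls without gene models higher in kidney in all 5 comparisons, standard errors from the deposited p, and recentring on the T cell identity list. Random draws used seed 1. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.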

Results

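T cells from the blood and the kidneys of Dahl salt-sensitive (SS) rats, an inbred model of salt-dependent hypertension, were profiled by RNA sequencing in 40 libraries. Each library came from a pool of 3 rats, and 4 libraries made up each of 10 groups, which paired circulating and kidney T cells from 5 groups of rats. The rats were of 2 types per the labels, SS/MCW and SS/CRL, which as background are colonies of the strain kept at different sites and on different base chows. At 10 weeks of age both types were sampled on low-salt chow (LS) and after 3 weeks of high-salt chow (HS), and SS/MCW rats on LS were also sampled at 7 weeks. Expression is given as the authors' FPKM, 1 value per group, so no spread among the 4 libraries can be printed beside any value and the depth of each library is unknown. Unless another test is named, a gene is said to have risen or fallen only where the Cuffdiff q in the authors' deposited table was under 0.05. Genes called largest are those with a symbol, at least 5 FPKM in the higher group and a value above 0 in both. Positions are those of the authors' gene models on build rn5.

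**Figure D1:**
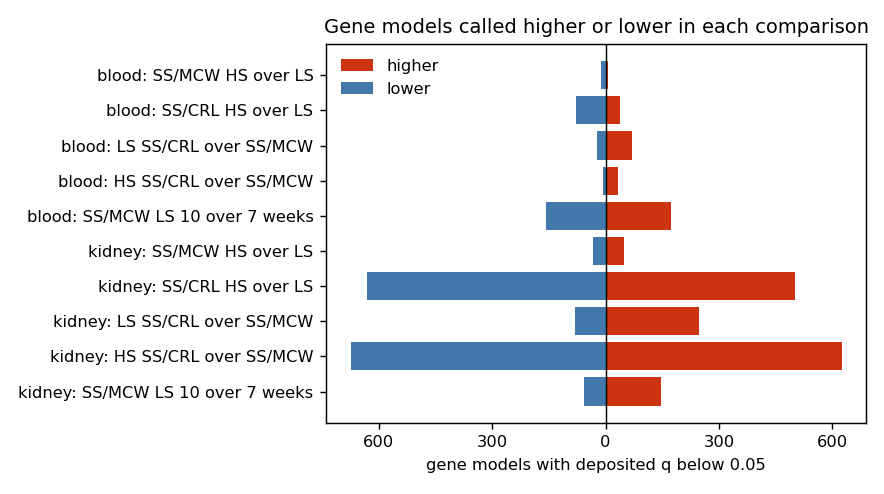
Gene models called higher (red, right) or lower (blue, left) at a deposited q below 0.05 in each of the 10 comparisons within blood or within kidney; the horizontal axis counts gene models. The kidney comparisons of SS/CRL rats on HS, against LS with 1130 calls and against SS/MCW rats with 1299, had more calls than the others.

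Kidney T cells were set against circulating T cells to ask how cells in the organ differ from those in blood. In all 5 groups of rats the T cell identity genes were called lower in the kidney cells. Nearly all oxidative phosphorylation genes, and part of the tubule and macrophage genes, were called higher in all of them. Cd3e, a chain of the T cell receptor complex (chromosome 8 from 47915615 to 47926788), lay between 739.8 and 874 FPKM in circulating cells and between 20.5 and 99.0 FPKM in kidney cells. The coreceptor gene Cd8a lay between 422 and 498 FPKM in blood and between 36.4 and 124 FPKM in kidney, and Cd4 between 116 and 135 against 4.23 to 19.1 FPKM. The leukocyte phosphatase gene Ptprc fell from at least 606 FPKM in blood to at most 44.0 FPKM in kidney in each of the 5 comparisons. All 17 matched members of the T cell identity list were lower in kidney in all 5 comparisons, and so were 11 of 13 naive and recirculating T cell genes and 21 of 32 ribosomal protein genes.

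Among gene models called the same way in all 5 comparisons, those with the largest median excess in kidney were Cryab, a small heat shock protein gene, Miox, an inositol-degrading enzyme of the proximal tubule, Slc34a1, a phosphate transporter of the same segment, Timp3 and Cdkl1. Slc34a1 lay between 404 and 2989 FPKM in kidney and did not exceed 0.209 FPKM in blood. Among those with the largest median deficit in kidney were the homing receptor genes Ccr7, with 299 to 388 FPKM in blood and 1.38 to 4.43 FPKM in kidney, and Ccr9, together with Mcart1l and Art2b. Umod, the main secreted protein gene of the thick ascending limb (chromosome 1 from 196127948 to 196141956), lay between 953 and 12856 FPKM in kidney and did not exceed 2.15 FPKM in blood, and passed in the SS/CRL comparisons but not in those of SS/MCW rats. Proximal tubule genes were higher in kidney in all 5 comparisons for 6 of 21 members and distal nephron genes for 8 of 19. The counts were 3 of 9 for podocyte genes, 5 of 16 for endothelial genes, 3 of 13 for fibroblast genes and 6 of 14 for tubular injury genes. These are counts of calls and understate the tubule excess, since Aqp1 is not among them with a median log2 fold change of 15.4. Among members with at least 1 FPKM in the higher tissue and a blood value above 0, none lay below 3276% of blood in the proximal tubule list. In the distal nephron list none lay below 271%.

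Energy and activation genes separated the tissues as well. The kidney libraries carried abundant tubule transcripts beside low levels of T cell genes, so neither these excesses nor changes in the kidney comparisons below are assigned to the T cells themselves. Of 35 oxidative phosphorylation genes 34 were higher in kidney in all 5 comparisons, as were 16 of 21 fatty acid oxidation genes and 10 of 19 glycolysis genes. The same held for 12 of 21 NADPH oxidase and redox genes, 8 of 15 sodium and osmotic response genes and 13 of 24 immediate early genes. Fos, an immediate early transcription factor gene, lay between 125 and 359 FPKM in kidney and between 4.30 and 5.26 FPKM in blood. Of 17 macrophage genes 9 were higher in kidney in all 5 comparisons, among them lysozyme (Lyz2) with 90.0 to 577 FPKM against 41.3 to 58.1 FPKM in blood. Of 18 cytotoxic genes 5 were lower in kidney in all 5 comparisons and none higher, and of 17 tissue-resident and effector memory genes 5 were lower and 2 higher.

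In all, 3356 gene models were higher in kidney and 2479 higher in blood in all 5 comparisons, of 18271 tested in each. The single comparisons gave 13117 calls in SS/MCW rats at 7 weeks, 9445 and 11487 in SS/MCW rats on LS and HS at 10 weeks, and 12115 and 12702 in SS/CRL rats on LS and HS. The median log2 fold change of genes with at least 5 FPKM in both tissues lay between -0.23 and -0.15, so that relative to other genes the kidney excess was slightly larger, and the kidney deficit slightly smaller, than the values show. In the SS/MCW HS comparison 62.5% of calls were higher in kidney, against 73.0% of the 3604 calls left when fold changes were recentred on that median and tested with a normal p. The share went from 57.9% to 62.5% and from 61.1% to 70.3% in SS/MCW rats on LS at 7 and 10 weeks. In SS/CRL rats it went from 58.9% to 57.6% on LS and from 60.1% to 60.6% on HS.

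T cell genes in kidney cells were expressed as a percent of their level in circulating cells of the same group of rats. The median over 17 genes was 3.33% in SS/MCW rats at 7 weeks. At 10 weeks it was 5.11% in SS/MCW rats on LS, 12.9% in SS/MCW rats on HS, 3.28% in SS/CRL rats on LS and 2.72% in SS/CRL rats on HS. For CD4 and CD8 lineage genes the medians were 6.35%, 9.71%, 21.0%, 7.01% and 4.80% in the same order.

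**Figure D2:**
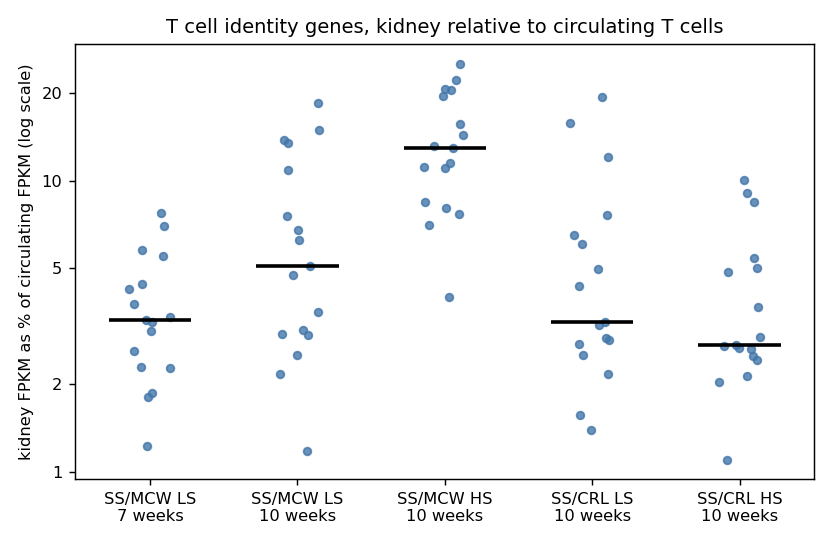
Kidney FPKM as a percent of circulating FPKM (log axis) for the 17 T cell identity genes, 1 point per gene, in the 5 groups of rats, with the median as a black bar. The median was 12.9% in SS/MCW rats on HS and between 2.72% and 5.11% in the other groups.

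High salt was compared with low salt in the kidney T cells of SS/MCW rats. Leukocyte genes of several kinds had higher values on HS, and hemoglobin genes fell. Rises were called for Ptprc (12.4 to 48.8 FPKM), for Itgb2, the shared chain of the leukocyte integrins (a log2 fold change of 2.17), for the natural killer receptor gene Klrb1c (2.63 to 15.4), for Rgcc (9.58 to 42.2) and for Rhebl1 (0.811 to 5.33). The largest falls among named genes were those of Hbb (645 to 56.0 FPKM), Hba2 (1333 to 137), the proximal tubule amino acid transporter gene Slc6a19 (21.1 to 2.92), Piwil1 (11.2 to 1.68) and Lrtm2 (6.25 to 0.944).

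All 17 measured T cell identity genes had a higher value on HS, with a median log2 fold change of 1.35, a value exceeded by none of 10000 random lists of like expression. Cd27, a costimulatory receptor gene (10.3 to 42.8 FPKM), and the adaptor gene Lcp2 (7.50 to 24.3) rose among 16 tested, and 14 did not pass. The count was 11 higher adjusted over the list alone. Cd4 rose from 7.44 to 21.2 FPKM with a q of 0.0462 in the authors' deposited table, where Cd3e stood at 42.1 and 110.3 FPKM on LS and HS with a q of 0.0527 and Cd8a at 98.2 and 138 FPKM with a q of 1.000. Of 17 cytotoxic genes tested Klrk1 rose (9.29 to 31.1 FPKM), with 5 adjusted over the list alone and a median of 1.43. Of 16 tissue-resident and effector memory genes Rgs1 rose (27.0 to 101), with 7 adjusted over the list alone, and of 22 immediate early genes Tnfaip3 rose (10.00 to 34.7), with 11 adjusted over the list alone. Satb1 rose (6.98 to 20.7 FPKM) among 13 naive T cell genes and Ctla4 (4.95 to 18.8 FPKM) among 12 regulatory T cell genes, and no Th1, interferon, MHC class II or inflammatory cytokine gene passed over all genes; adjusted over the list alone the counts were 1, 1, 0 and 1.

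Markers of other cells moved along with the T cell genes. The median log2 fold change was 0.71 for macrophage genes, of which Gpnmb rose (15.2 to 56.3 FPKM; 5 of 15 adjusted over the list alone), 1.18 for natural killer cell genes, 1.27 for B cell genes and 1.01 for MHC class II genes. It was -0.64 for proximal tubule genes, with 0 of 20 passing, -0.83 for endothelial genes, with 4 lower adjusted over the list alone, and -1.20 for fibroblast and mural genes, with 3 lower adjusted over the list alone. Cuffdiff made 84 calls among 19385 tested gene models, 50 higher and 34 lower, and in 39 of them 1 of the groups was listed at 0. No call remained at q under 0.01, because the smallest q in this table was 0.0179. In all, 828 gene models had an unadjusted p under 0.05, a smaller share than unchanged genes would give, and a normal p of the deposited test statistic gave 6 calls.

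High salt was compared with low salt in the kidney T cells of SS/CRL rats in the same way. Proximal tubule transporter and enzyme genes fell, and some endothelial and osmotic response genes rose. Slc22a6, the organic anion transporter OAT1, fell from 863 to 164 FPKM, the urate transporter gene Slc22a12 from 479.7 to 102, the glucose transporter gene Slc5a2 (SGLT2) from 65.9 to 14.5 and the fatty acid transporter gene Slc27a2 from 242 to 74.0. Of 20 proximal tubule genes 12 fell, 7 did not pass and 1 rose, Pck1, an enzyme of gluconeogenesis (364 to 1071 FPKM). Adjusted over the list alone the counts were 14 and 1. The median log2 fold change of the list was -0.99, and its calls were more frequent than those among other genes (two-sided Fisher's exact test, adjusted p = 9.85e-11 over the lists). Genes of 1 segment can move together, so this p-value does not measure variation among rats. The phosphate transporter gene Slc34a3 (chromosome 3 from 2429662 to 2435216) fell from 116 to 17.3 FPKM, Akr1c1 from 235 to 38.8, Prima1 from 41.0 to 5.84 and Prkcb from 37.8 to 3.00.

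Among the largest rises were those of Ttbk2 (1.26 to 20.1 FPKM), MAMDC2 (0.476 to 6.60), Tcp11l1 (0.837 to 8.45) and Nkain4 (3.03 to 14.8). Of 14 sodium and osmotic response genes 4 rose, namely aldose reductase Akr1b1 (39.0 to 76.8 FPKM), the betaine transporter Slc6a12 (19.0 to 35.2), Slc6a6 and Atp1b3, and 1 fell, the kinase gene Sgk1 (154 to 72.0). Adjusted over the list alone 6 rose and 1 fell. Of 15 endothelial genes 5 rose, among them Plvap (4.48 to 10.7 FPKM), Cdh5 (4.00 to 8.88) and Esam (71.2 to 125), with 8 higher and 1 lower adjusted over the list alone. In the distal nephron list the water channel gene Aqp2 (209 to 346 FPKM), Hsd11b2 (70.1 to 116) and Wfdc2 rose and 16 of 19 did not pass (Fisher's exact adjusted p = 0.419), with 6 higher and 1 lower adjusted over the list alone. Lcn2, Cd24 and Vim rose among 13 tubular injury genes, Hk1, Slc2a1 and Pkm among 17 glycolysis genes, and Thbs1, Ctgf and Sparc among 12 matrix genes. Egr1, Junb and Gadd45b rose among 21 immediate early genes, and adjusted over the list alone the counts were 5, 4, 7 and 6 in this order.

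T cell identity genes had a median log2 fold change of -0.35 in this comparison. Lat, a T cell receptor adaptor gene, fell from 100.2 to 57.3 FPKM, 13 of 14 did not pass, and 3 fell adjusted over the list alone. Cd3e stood at 27.3 and 22.6 FPKM, Cd4 at 5.28 and 4.68, Cd8a at 49.4 and 40.3 and Ptprc at 13.1 and 8.61 on LS and HS. Hemoglobin genes fell, as Hba1 did from 1716 to 355 FPKM, and 1 macrophage gene of 13 fell, Apoe (381 to 213). Of 20501 gene models tested, 500 rose and 630 fell; 304 of these calls had a group listed at 0. A normal p of the deposited test statistic left 17 calls, all of them lower on HS, and without the gene models that were higher in kidney than in blood in all 5 comparisons 787 calls remained.

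Whether salt acted differently in the kidney cells of the 2 rat types was tested gene by gene on the difference of the log2 fold changes. No gene model passed of 16422 (normal z test on the Cuffdiff statistics, Benjamini-Hochberg), with 109 at an unadjusted p under 0.05. That is a smaller share than the 0.05 that unchanged genes would give. The z values had a standard deviation of 0.61, against 1.08 with standard errors from the deposited p. The standard errors of the main test were thus too large across genes as a set, and its lack of calls does not show that salt acted alike. In simulated data with those same standard errors the test recovered 9.5% of differences of 3 log2 units. That simulation cannot show whether the standard errors were right. With standard errors taken from the deposited p, chosen after the data were seen, 60 passed, 47 of them with the higher effect in SS/MCW rats. Among the genes with the largest difference in favor of SS/MCW were Fmnl1, with 2.36 on the log2 scale, Dgka with 2.43, Dock2 with 2.76 and Ptprc with 2.58; toward SS/CRL they were Thbs2, Mgp, Tm4sf1, Sh3gl3 and Eltd1. For the lists, the salt effect on T cell identity genes was higher in SS/MCW for 16 of 16 genes, by a median of 1.57, above that of every random list. The median difference was 2.07 for 15 cytotoxic genes, 0.81 for 14 macrophage genes, -1.69 for 15 endothelial genes and -0.64 for 15 sodium and osmotic response genes. Effects on single genes had an r of -0.0682 between the rat types (Pearson, across 16422 gene models, which are not independent replicates; Spearman's rho was -0.00542).

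**Figure D3:**
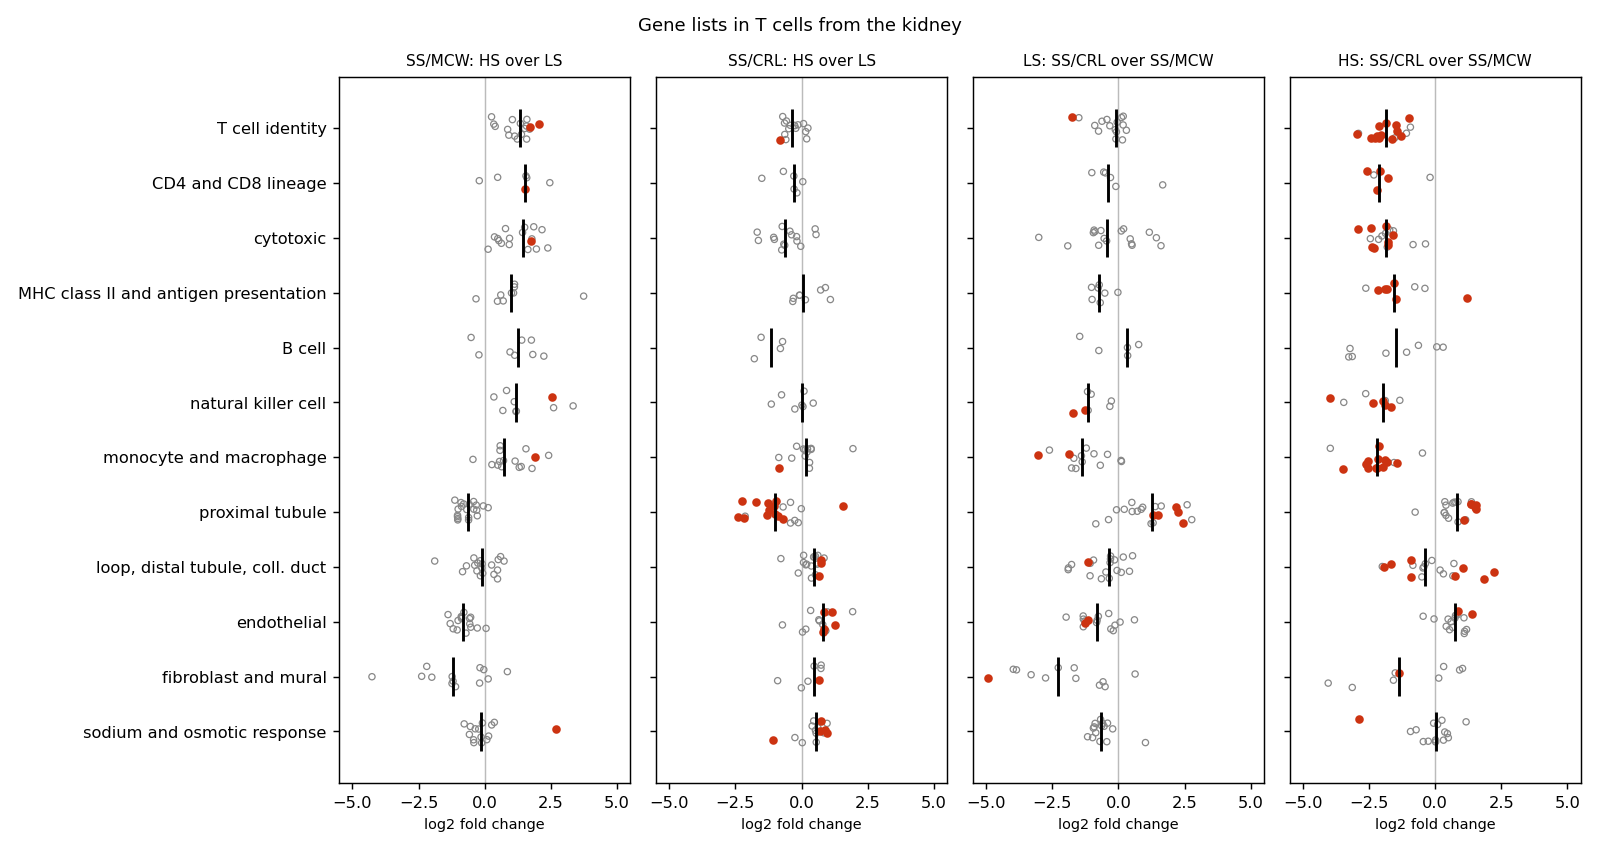
Log2 fold changes of the members of 12 gene lists in kidney T cells, 1 point per gene with finite values, for salt in each rat type and for rat type on each chow; red filled points have a deposited q below 0.05, grey open points do not, and black bars are medians that leave out members listed at 0 in a group. Proximal tubule genes lie to the left for salt in SS/CRL rats and to the right for SS/CRL against SS/MCW on LS, with list medians of -0.99 and 1.27, and T cell identity genes lie to the left for SS/CRL against SS/MCW on HS, with a median of -1.84.

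The rat types were compared on low salt to ask how the colonies differ before a salt challenge. Kidney cells of SS/CRL rats had higher values of proximal tubule genes than those of SS/MCW rats, while single fibroblast, macrophage and endothelial genes were lower. Slc34a3 rose from 5.98 to 113 FPKM in SS/MCW to SS/CRL, with a q of 0.00524 in the authors' deposited table, followed by Garnl3 (3.17 to 26.0 FPKM), Prima1 (5.89 to 40.2), Rdh5 (5.08 to 30.8) and Akr1c1 (39.7 to 231). Of 20 proximal tubule genes 5 were higher in SS/CRL and 15 did not pass, with 13 higher adjusted over the list alone and a median log2 fold change of 1.27. Slc22a6 rose from 154 to 845 FPKM, Slc22a12 from 104 to 470.1 and the transcription factor gene Hnf4a from 234 to 666. The collagen gene Col3a1 was lower in SS/CRL rats (9.11 to 0.299 FPKM), as were Fabp4 (63.5 to 3.54), the complement gene C1qb (42.9 to 5.26), Mgp (309 to 38.8) and Ifi27l2b (391 to 77.4).

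Cd3d was the T cell identity gene that passed on low salt, falling from 112 to 33.0 FPKM, with 13 of 14 not passing, 2 lower adjusted over the list alone and a median of -0.11. Cd3e stood at 41.2 and 26.8 FPKM in SS/MCW and SS/CRL rats, Cd4 at 7.26 and 5.17, Cd8a at 97.1 and 48.4 and Ptprc at 12.2 and 12.9. C1qb and Gpnmb fell among 14 macrophage genes (6 adjusted over the list alone, median -1.38), Fcer1g and Tyrobp among 7 natural killer cell genes, and Pecam1 and Ptprb among 16 endothelial genes (6 adjusted over the list alone, median -0.82). The kidney injury gene Havcr1 (KIM-1) fell from 22.5 to 5.36 FPKM and the fibronectin gene Fn1 from 12.1 to 3.32, while in the fibroblast and mural list 1 of 12 genes passed (3 lower adjusted over the list alone, median -2.27). In total 246 gene models rose and 80 fell of 18032 tested, with a group listed at 0 in 89; a normal p of the test statistic left 5 calls.

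On high salt the kidney cells of SS/CRL rats had far lower levels of T cell, natural killer cell and macrophage genes than those of SS/MCW rats. Cd3e fell from 114 to 23.3 FPKM in SS/MCW to SS/CRL, Cd4 from 21.9 to 4.81, Cd8a from 142 to 41.5 and Ptprc from 50.5 to 8.90, each with a q of 0.00149 in the authors' deposited table. Of 17 T cell identity genes 13 fell and none rose (13 adjusted over the list alone), with a median log2 fold change of -1.84 and a Fisher's exact adjusted p of 5.78e-12. The falls spread over T cell states, with 4 of 6 lineage genes, 6 of 13 naive genes such as Lef1 (15.7 to 3.20 FPKM), and 8 of 16 tissue-resident genes such as Cxcr3 (28.9 to 4.07) and Cd69. They also took in 8 of 17 cytotoxic genes such as Klrk1 (32.2 to 4.22 FPKM) and Tbx21, 3 of 10 Th1 genes, 4 of 12 regulatory T cell genes and 2 of 6 checkpoint genes. Adjusted over the list alone the counts were 5, 7, 10, 10, 3, 5 and 3.

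Macrophage genes fell in 12 of 15 cases (13 adjusted over the list alone, median -2.20), among them lysozyme Lyz2 (663 to 113 FPKM), the growth factor receptor gene Csf1r (74.8 to 12.8), Gpnmb (58.1 to 5.20) and C1qb (32.9 to 7.08). In the natural killer cell list 5 of 9 genes fell, as did 5 of 9 MHC class II and antigen presentation genes, among them Cd74 (990.3 to 354 FPKM), while Cd40 rose. Of 21 NADPH oxidase and redox genes 6 fell, with the phagocyte subunit genes Cybb (19.9 to 4.19 FPKM), Ncf1 and Rac2 among them, and Gpx1 rose; adjusted over the list alone 7 fell and 5 rose. Inflammatory cytokine and chemokine genes fell in 5 of 17 cases (10 adjusted over the list alone), including Il1b, Ccl2, Ccl3 and Tgfb1, and 8 of 22 immediate early genes fell (12 adjusted over the list alone). The gene models with the largest falls were Cd300le (17.6 to 1.08 FPKM), Ntng2 (11.6 to 0.730), Klrb1c (15.9 to 1.01), Fcnb (16.4 to 1.36) and Il21r (18.5 to 1.65).

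Kidney epithelial genes went in both directions on high salt. Proximal tubule genes rose in 6 of 20 cases (11 higher and 1 lower adjusted over the list alone, median 0.82), such as Fbp1 (199.7 to 576 FPKM), Gatm (397 to 1115) and Hnf4a (121 to 347). In the distal nephron list 4 of 19 rose, Fxyd4 (21.1 to 99.0), Aqp2 (98.3 to 355), Calb1 and Aqp3, and 4 fell, the sodium-potassium-chloride cotransporter gene Slc12a1 (654 to 171), Egf (55.9 to 17.8), Cldn10 and Wfdc2. Emcn and Esam rose among 15 endothelial genes, and Havcr1, Krt19 and C3 fell among 14 tubular injury genes, 3 also adjusted over the list alone. The largest rises were those of Tcp11l1 (0.953 to 8.68 FPKM), the joint Edc4 and NRN1L gene model (2.87 on the log2 scale), Psmb11 (1.61 to 10.3), Ccl9 (3.60 to 21.2) and Piwil1 (1.72 to 8.97). There were 625 higher and 674 lower calls among 22692 gene models tested, 394 of them with a group listed at 0. Of the 2235 tested gene models that were higher in blood than in kidney in all 5 comparisons, 350 fell and none rose. A normal p of the test statistic left 22 calls, of which 22.7% were higher, against 48.1% of the main calls.

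The rat type effects on the 2 chows shared 47 higher and 29 lower calls, where 4.87 and 2.56 are expected for unrelated lists, and had an r of 0.327 across 16579 gene models. Their difference passed for no gene model of 16579, with 106 at an unadjusted p under 0.05, a smaller share than unchanged genes would give. With standard errors from the deposited p 17 passed. This difference is the contrast of 4 groups behind the difference of salt effects above, read the other way, and adds no further test. Of the 630 gene models that fell with salt in SS/CRL rats, 174 were among the 246 that were higher in SS/CRL than SS/MCW rats on LS, against 8.92 expected. These comparisons share the SS/CRL LS group, which alone links them, so the expected number is too low. The r between them was -0.660 against -0.464 in simulated unchanged groups, while the covariance was -0.744 against -1.72, or -0.524 with standard errors from the deposited p, so the values do not separate a shared response from the shared group.

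Age was compared in SS/MCW rats on low salt, at 10 against 7 weeks. Single genes of matrix, injury and hemoglobin lists and 3 macrophage genes rose in the kidney cells, with 1 of 17 matrix genes, 2 of 14 tubular injury genes and 2 of 10 erythroid genes passing (2, 2 and 4 higher adjusted over the list alone). The genes with the largest rise were Col3a1 (0.270 to 9.15 FPKM), the lipid carrier gene Fabp4 (1.98 to 64.1), Serf1 (4.38 to 56.2), decorin Dcn (1.30 to 12.3) and Havcr1 (2.53 to 23.2), and Hba2 rose from 229 to 1333 FPKM. Those with the largest fall were Wfdc1 (35.5 to 5.84 FPKM), Sfrp2 (63.0 to 11.3), the prostaglandin synthase gene Ptgs2 (17.9 to 4.14), Cdh3 (29.7 to 8.78) and Gp2 (49.1 to 14.8). C1qb, Gpnmb and Apoe rose among 14 macrophage genes (8 adjusted over the list alone, median 1.13), Lag3 rose among 4 checkpoint genes (19.5 to 71.5 FPKM), and Slc6a6 rose and the sodium channel gene Scnn1a fell (47.9 to 18.2 FPKM) in the sodium list. Of 16 T cell identity genes Cd3d rose (38.4 to 114 FPKM), 15 did not pass and 3 rose adjusted over the list alone. Cd3e stood at 29.7 and 42.1 FPKM at 7 and 10 weeks, Cd4 at 6.45 and 7.43, Cd8a at 44.7 and 98.2 and Ptprc at 11.8 and 12.4. The distal nephron list had a median of -0.87, with 9 lower and 3 higher adjusted over the list alone and Fxyd4 higher over all genes. In total 146 gene models rose and 56 fell of 18869 tested, and a normal p of the test statistic left 7. Age and salt in SS/MCW rats share the LS group at 10 weeks, and 12 gene models fell with salt and rose with age, against 0.276 expected. The r between them was -0.703 against -0.486 in simulated unchanged groups, while the covariance was -0.719 against -3.72. With standard errors from the deposited p the simulated r was -0.463 and the simulated covariance -0.618. These values do not separate a shared response from the shared group.

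In circulating T cells, salt changed few genes in SS/MCW rats. The 6 higher and 12 lower calls included 3 gene models with a symbol, among them Stub1, a ubiquitin ligase gene (chromosome 10 from 15003669 to 15012978), which fell from 413 to 74.1 FPKM. Cd3e stood at 693 and 777 FPKM on LS and HS, Cd4 at 118 and 104, Cd8a at 385 and 438 and Ptprc at 679 and 600.3. Ribosomal protein and oxidative phosphorylation genes had medians of 0.36 and 0.29 with no member passing, at percentiles 100 and 99.98 of random lists of like expression. Markers of other cells shifted by as much, with medians of 0.32 for B cell, 0.29 for natural killer cell, 0.29 for platelet and 0.32 for MHC class II genes and no member passing, while all 3 tested neutrophil genes were lower adjusted over the list alone, with none passing over all genes. Of 16885 gene models tested 1076 had an unadjusted p under 0.05, none had a q under 0.01, since the smallest was 0.0469, and a normal p of the test statistic gave 10 calls.

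Circulating cells of SS/CRL rats on high salt had more hemoglobin and platelet transcript and less of 2 neutrophil genes than those on low salt. Stub1 rose from 57.5 to 280.3 FPKM, opposite to SS/MCW rats, followed by Rps4y2 (1.86 to 5.60), the phospholipase gene Pla2g2a (2.84 to 6.22), platelet factor Pf4 (22.8 to 44.1) and Hba1 (38.7 to 74.8). S100a9 fell from 13.8 to 3.54 FPKM, S100a8 from 12.3 to 4.40, 3 gene models named RPS29 fell, and so did Il1b (1.96 to 0.786), Nfkbia (131 to 87.9) and Tnfaip3 (64.6 to 43.5) and the glucocorticoid target Klf9 (41.0 to 27.0). In all, 3 of 8 erythroid genes and 2 of 10 platelet genes rose (4 and 4 adjusted over the list alone), and 2 of 4 neutrophil genes fell. Of 13 inflammatory cytokine and chemokine genes Il1b alone passed, with 1 higher and 1 lower adjusted over the list alone; 4 measured members were higher and 4 lower. Traces of kidney transcripts rose too, with Fxyd2 going from 0.426 to 1.32 FPKM and Umod listed at 0 on LS and at 1.93 FPKM on HS. Cd3e, Cd4, Cd8a and Ptprc did not pass. Of 17169 tested, 37 gene models rose and 78 fell, and a normal p of the test statistic left 9. The circulating salt effects of the 2 rat types had an r of 0.389 across 13293 gene models, which are not independent replicates (Spearman's rho was 0.578). These comparisons share no group. They shared 5 lower calls, where 0.0527 are expected, and no higher call, and 1 gene model was lower in SS/MCW and higher in SS/CRL rats.

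On low salt the circulating cells of SS/CRL rats had higher cytotoxic, B cell and MHC class II genes than those of SS/MCW rats. Ccl5, a chemokine gene of cytotoxic cells, rose from 56.5 to 229 FPKM, the granzyme genes Gzma and Gzmk from 1.82 to 6.53 and from 6.85 to 22.9, and the B cell and signaling genes Fcrla and Syk from 3.72 to 7.97 and from 2.59 to 5.46. Rises were called for 7 of 18 cytotoxic genes (12 adjusted over the list alone, median 0.49) and for 9 of 14 B cell genes (11 adjusted over the list alone, median 0.82), such as Pax5 (6.14 to 12.6 FPKM). They were also called for 5 of 8 MHC class II genes (7 adjusted over the list alone), such as Cd74 (106 to 181 FPKM), and for 3 of 11 natural killer cell genes (6 adjusted over the list alone). Stub1 (424 to 57.4 FPKM), the Tm7sf2 and Vps51 gene model, the cytokine signaling inhibitor Socs1 (13.7 to 7.64) and Ddx5 fell. Cd3e stood at 712 and 672 FPKM in SS/MCW and SS/CRL rats, and Cd4, Cd8a and Ptprc did not pass either. Of 17004 tested, 70 rose and 22 fell, and a normal p of the test statistic left 11.

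On high salt the cytotoxic difference was seen again, with 6 of 17 cytotoxic genes higher in SS/CRL rats (8 adjusted over the list alone, median 0.44). Gzma rose by 2.07 on the log2 scale. Gzmk rose from 8.92 to 24.5 FPKM, Ccl5 from 82.8 to 228, the signaling adaptor gene Tyrobp from 13.7 to 33.8 and Stub1 from 74.5 to 272, while Rps9 (758 to 424) and the phosphatase gene Dusp2 (38.8 to 24.7) fell. None of 14 B cell genes passed over all genes in Cuffdiff, 7 rose adjusted over the list alone and the median was 0.59; for 9 MHC class II genes the counts were 0 and 4. Among 8 erythroid genes 3 rose, with Hba1 going from 34.0 to 72.6 FPKM, and Cd3e, Cd4, Cd8a and Ptprc did not pass. Of 16995 tested, 34 gene models rose and 7 fell, and a normal p of the test statistic left 8, of which 37.5% were higher against 82.9% of the Cuffdiff calls. The rat type effects on LS and HS shared 18 higher calls, where 0.127 are expected, and the difference between them passed for 6 gene models, of which Stub1 has a symbol. Of 13150 tested for this difference, 23 had an unadjusted p under 0.05, a smaller share than unchanged genes would give.

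Circulating cells of SS/MCW rats had less platelet and hemoglobin transcript at 10 than at 7 weeks. Of 13 platelet genes 5 fell (8 adjusted over the list alone, median -1.58), among them Pf4 (96.9 to 25.9 FPKM), Gp1bb (7.27 to 1.87) and Treml1, and 3 erythroid genes fell, as Hba1 did from 89.4 to 27.6 FPKM. The neuropeptide gene Npy (21.8 to 5.07 FPKM), Pla2g2a (12.1 to 3.11) and Nrgn (9.20 to 2.49) fell, and Klhl11 (2.81 to 6.81), the acetyltransferase gene EP300 (4.65 to 10.6), Pank3, Ptar1 and Lcor rose. The osmotic transcription factor gene Nfat5 rose from 10.0 to 16.3 FPKM, the integrin gene Itga4 from 41.7 to 76.7 and the regulatory T cell gene Ikzf2 from 7.61 to 11.5. Of 35 oxidative phosphorylation genes Uqcrh and Ndufb3 fell (12 adjusted over the list alone, median -0.40). Cd3e, Cd4, Cd8a and Ptprc did not pass. Of 17103 tested, 174 rose and 157 fell, and a normal p of the test statistic left 8.

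**Figure D4:**
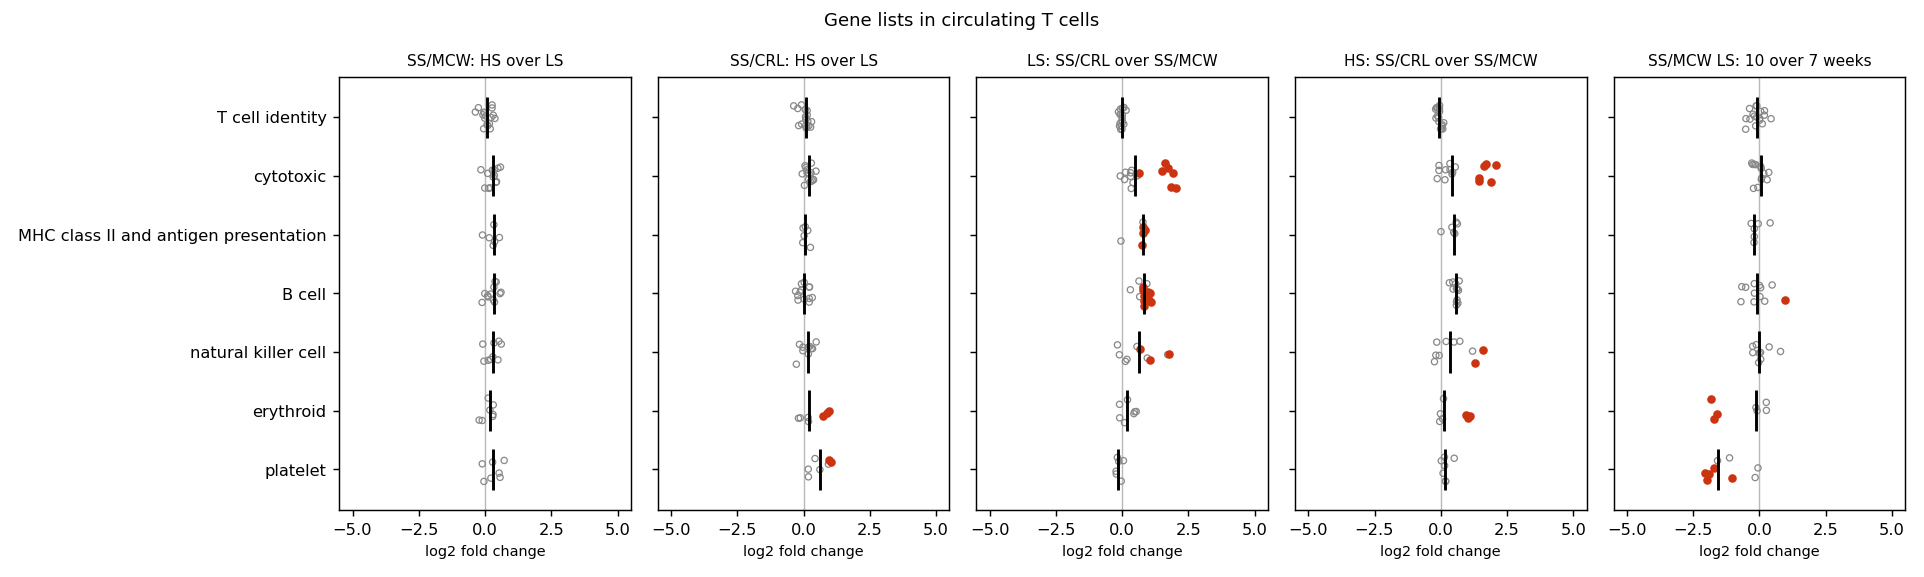
Log2 fold changes of the members of 7 gene lists in circulating T cells, 1 point per gene with finite values, in the 5 comparisons; red filled points have a deposited q below 0.05, grey open points do not, and black bars are medians over the plotted points. T cell identity genes lie near 0 throughout, cytotoxic and B cell genes lie to the right for SS/CRL against SS/MCW on LS, with medians of 0.49 and 0.82, and platelet genes lie to the left for age, with a median of -1.58.

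The same contrast in kidney and in circulating cells gave effects with little correlation across genes, which are not independent replicates. The r between tissues was 0.0403 for salt in SS/MCW rats, 0.000298 for salt in SS/CRL rats, 0.00945 and -0.0904 for rat type on LS and HS, and -0.00663 for age. The difference between tissues passed for 1, 4, 1, 9 and 1 gene models in that order, with 29, 102, 34, 289 and 59 at an unadjusted p under 0.05. The numbers tested were 11126, 10624, 10510, 11327 and 10921, so each count is a smaller share than the 0.05 that unchanged genes would give. The z values had standard deviations of 1.57, 1.26, 1.24, 0.72 and 5.22, so the standard errors did not match the spread of the differences. For lists, the effect of rat type on HS was lower in kidney than in circulating cells for 17 of 17 T cell identity genes, by a median difference of -1.80, and for 15 of 15 cytotoxic genes, with a median difference of -2.49. The salt effect in SS/MCW rats was higher in kidney for 16 of 17 T cell identity genes, with a median difference of 1.28.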

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

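The tests of T cells alone and of scaling in the first pattern below, and all tests of the second pattern, were chosen after the result was seen. The first pattern's test of a larger leukocyte share was set before its result was seen, and the test of added circulating RNA was set before its own result but after that first value was known. The use of kidney groups outside the comparison, for both of these, was chosen after the results were seen.

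Effects that differed between groups by the z test of the difference included these. In circulating cells the salt effect on Stub1 was lower in SS/MCW than in SS/CRL rats by a difference of -4.76 on the log2 scale, and the rat type effect on Stub1 was higher on HS than on LS by 4.76. This is the same contrast of 4 groups read the other way. The salt effect in SS/CRL rats was lower in kidney than in circulating cells for Hba1 (-3.23), Hba2 (-2.92) and Hbb (-2.79), which encode hemoglobin chains of red cells. The effect of rat type on HS was lower in kidney than in circulating cells for Fcer1g (-3.09), Tyrobp (-3.27), Lyz2 (-2.94) and Il2rb (-3.03), and higher for Nkx2-1 (3.72). For Nkx2-1 the log2 fold changes were 1.40 in kidney and -2.32 in circulating cells. The circulating part rests on low values, 0.364 FPKM in SS/CRL and 1.82 FPKM in SS/MCW rats.

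The first pattern was the higher level of leukocyte genes in kidney cells of SS/MCW than SS/CRL rats on HS. The macrophage median of -2.20 argued against a change within the T cells alone, with 4 of 4 lists of other leukocytes below -1. The authors' scaling was not settled by the median of 0.0212 over all genes of at least 5 FPKM. That median lay between -0.0430 and 0.0449 in all kidney comparisons, and scaling the groups to each other can itself place it near 0. A larger share of leukocyte RNA was expected to bring at least 70% of circulating-high gene models within 1 log2 unit of the T cell identity median, and 22.6% were, which met the bound set beforehand for excluding it. That bound was set aside afterwards, because it assumed kidney cells lack these transcripts, whereas only 9.97% of 2216 gene models were under 10% of their circulating level in all 3 kidney groups outside this comparison, and 81.0% of those 221 lay within 1 of the T cell identity median. Circulating RNA added to the kidney cells' own put 70.3% of gene models closer to its prediction than to no change, just past its bound of 70% and with kidney values shared by prediction and observation, against 72.0% with the SS/CRL LS kidney level as the base, and more leukocytes in these kidneys, a higher yield of them, or an effect of rat type or chow may each lie behind it.

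The second pattern was the higher level of proximal tubule genes in kidney cells of SS/CRL than SS/MCW rats on LS. More kidney RNA of every kind would be expected to raise distal nephron, fibroblast and endothelial genes. The fibroblast and mural median was below 0, no distal nephron median is given here, and the endothelial median was -0.82. Endothelial genes were also lower on HS than on LS in SS/MCW rats, so a high level in the SS/MCW LS group could give that median. The test therefore does not exclude more kidney RNA in the SS/CRL LS cells. An equal rise of all proximal tubule RNA stayed open, since 65% of 20 members lay within 1 log2 unit of their median, between the bounds set for and against it. Rat type and diet before the salt period, with a median of 1.27, could not be separated from it, since each rat type and diet had 1 group of rats.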

How the results depend on the processing

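The calls without kidney-high gene models, the standard errors from the deposited p and the recentring on the T cell identity list were chosen after the data were seen. No paired analysis was possible because each group has 1 pooled value in the tables. Leave-one-out, the replicate block, the pseudocount of 0.1 on library values, and edgeR against DESeq2 were planned for values per library and were not run. Depth is unknown, so what it limits was not tested.

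At q under 0.01, 6 of 15 counts of calls stayed within 1.5 times. The other counts were 0 for circulating salt in SS/MCW and in SS/CRL rats, 0 and 0 for circulating rat type on LS and HS, 124 for circulating age, 0 and 752 for kidney salt in SS/MCW and SS/CRL rats, 196 for kidney rat type on LS and 96 for kidney age. The counts of 0 follow from the smallest q in those tables, which lay above 0.01.

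The normal p of the test statistic moved all 15 counts, each to a lower value. Unlike the deposited p, which does not go below 5e-05, it has no floor, so it was not the larger p for every gene model. It gave 10, 9, 11, 8 and 8 calls for circulating salt in SS/MCW and SS/CRL rats, rat type on LS and HS, and age, and 6, 17, 5, 22 and 7 for the same kidney comparisons. For kidney against circulating cells it gave 5597 in SS/MCW rats at 7 weeks, 2450 and 3498 on LS and HS at 10 weeks, and 4859 and 5055 in SS/CRL rats on LS and HS. Recentred as well, the counts were 10, 10, 11, 8 and 5 in circulating cells, 6, 15, 5, 22 and 7 in kidney cells, and 5585, 2492, 3604, 4870 and 5038 between tissues. The share of higher calls under the normal p was 50%, 44.4%, 63.6%, 37.5% and 25% in circulating cells, against 33.3%, 32.2%, 76.1%, 82.9% and 52.6%. In kidney cells it was 50%, 0%, 60%, 22.7% and 85.7%, against 59.5%, 44.2%, 75.5%, 48.1% and 72.3%.

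All 15 counts stayed within 1.5 times with a minimum of 1 FPKM, and the 5 kidney counts did so without kidney-high gene models. Recentring on the T cell identity median changed the calls among circulating-high gene models from 24 to 1424 for kidney salt in SS/MCW rats. The calls went from 7 to 1 for rat type on LS, from 348 to 1783 for rat type on HS and from 6 to 1 for age. For salt in SS/CRL rats the count was 35 before and after. The direction turned over: in SS/MCW salt 2 were higher and 1422 lower after recentring, where all had been higher, and on HS 1780 were higher and 3 lower, where all had been lower. For both of these the subtracted medians, 1.35 and -1.84, were larger in size than most of the changes, which turns their sign. For SS/CRL salt the subtracted median was -0.27, which differs from the list median given above for this comparison over members of at least 1 FPKM. All 35 calls after recentring were higher there, where 9 had been higher and 26 lower before. Whether they were the same gene models was not tested.

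With standard errors from the deposited p the differences that passed were 60 and 17 for kidney salt and rat type effects, 1 and 3 for the circulating ones, and 5, 160, 8, 359 and 34 for kidney minus circulating effects of salt in SS/MCW and SS/CRL rats, rat type on LS and HS, and age. At least 5 FPKM gave 3 for kidney minus circulating salt in SS/MCW rats, and q under 0.01 gave 3 for rat type on HS. The other 8 counts under each stayed within 1.5 times, as did the 4 tested with both pairs of tables. The cause was not tested.

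The median of the cell cycle list for kidney against circulating cells in SS/CRL rats on HS was below 0, and its mean was 0.13. With the mean, 535 list values kept side and direction, 31 became stronger and 56 weaker; without the filter the counts were 573, 31 and 20, and with unmatched random lists 533, 16 and 75. Named gene fold changes were unmoved by recentring in 1007 cases, and a pseudocount of 1 moved 222 of them. Among correlations 13 stayed and 6 moved at 5 FPKM. The counts of genes called alike in all 5 tissue comparisons stayed within 1.5 times with each comparison left out and at q under 0.01.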

Other observations

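The kidney cells of SS/MCW rats on LS at 10 weeks had a higher value of the collagen gene Col3a1 than the other kidney groups. Col3a1 was at 9.15 FPKM in this group and at 0.476 FPKM in SS/MCW rats on HS, at 0.270 FPKM at 7 weeks and at 0.299 FPKM in SS/CRL rats on LS, and it was at 0.724 FPKM in SS/CRL rats on HS. The hemoglobin gene Hba2 was high in both LS groups at 10 weeks, at 1333 FPKM in this group, at 137 FPKM on HS and at 229 FPKM at 7 weeks, and at 958 and 217 FPKM in SS/CRL rats on LS and HS. Whether 1 of the 4 pools of a group carries these values was not tested here.

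Cytotoxic genes in kidney cells had a median of 40.6% of their circulating level in SS/MCW rats at 7 weeks, 40.8% and 117% on LS and HS at 10 weeks, and 23.1% and 14.2% in SS/CRL rats on LS and HS, with single members between 1.87% and 1224%. Natural killer cell genes had medians of 31.0%, 41.0%, 89.6%, 12.5% and 22.04% in the same order, and tissue-resident and effector memory genes 73.1%, 62.3%, 99.0%, 41.3% and 36.2%.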
